A study of Homo sapiens with 12 samples.

How the data were processed

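Gene expression was measured in lung tissue from 12 people, 6 with active pulmonary sarcoidosis and 6 with normal lung anatomy, each on 1 Affymetrix Human Genome U133 Plus 2.0 array. This array reads biotin-labelled copies of total RNA with short probes grouped into probe sets, and most genes are covered by several probe sets. Per the labels, 11 samples were surgical biopsies and 1, sarcoidosis replicate 1, was a transbronchial biopsy, a small piece of lung taken through the airway wall. The replicate numbers name different people.

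The deposited values are log2 expression per probe set, and RMA is the tool named in the submitters' processing notes. RMA corrects the background of each array, quantile normalises the probes between arrays and summarises each probe set by median polish. The version of RMA and the probe set definition are not given in the sources used here. Because quantile normalisation gives all arrays nearly the same distribution, the values cannot show a change in the total amount of RNA, and a difference is relative to the other genes on the array. RMA values of dim probe sets level off above 0, so a fold change against a group in which a gene is dim understates the change. The array medians of the deposited log2 values ran from 6.42 to 6.49, and they were used as deposited. No scan dates or hybridisation batches were analysed here. Arrays have no read depth, and the number of arrays limits the precision: the median standard error of a log2 difference over all genes was 0.119.

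Probe sets were named from the platform annotation table, with gene identifiers matched to the RefSeq annotation of human assembly GRCh38.p14, which was used for names only. Of 54675 probe sets, 41091 had 1 gene, 1801 had several genes, 62 were Affymetrix controls and 11721 were unnamed in the table used here. Of the probe sets with 1 gene, 41037 matched a RefSeq gene identifier and 54 kept the name in the platform table. The control probe sets and 95 probe sets of sex-linked genes fixed in advance were left out, which left 54518 probe sets. Each gene was represented by the probe set with the highest mean over the 12 arrays among those annotated to that gene alone, which gave 19740 genes. No filter on dim probe sets was applied. No coordinates are given, since the values come from probe sets and no genome build is named for them.

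The comparison of sarcoidosis with normal lung was fitted with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with default settings, group as the only term). A difference is sarcoidosis minus normal on the log2 scale, given with the standard error of limma's moderated fit, and group means are given with their SD. P-values were adjusted by the Benjamini-Hochberg method over genes, and a gene is said to have risen or fallen when its adjusted p was under 0.05. Adjusted p-values of single genes come from this limma fit unless another test is named.

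Before the data were examined, 38 lists of cell type markers and pathways were fixed. Of their 627 genes, 585 were measured here, and 27 genes stood in more than 1 list. Each list was compared with all other genes by camera with its preset inter-gene correlation of 0.01, adjusted over the lists. Beside it stand camera with a correlation estimated from the data, and the number of members that rose or fell over all genes and adjusted over the list alone. An exact permutation test of the mean of each list per array over all 924 regroupings of the 12 arrays was added after the design was fixed. The smallest p it can give is 0.00216.

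The genes named in the text were chosen by a rule fixed before the data were examined. It takes the 15 largest rises and the 15 largest falls among genes that passed the test and whose groups did not overlap. Immunoglobulin and T cell receptor segment genes and probe sets of several genes are left out of that part. It then takes, for each list, up to 4 members with the smallest adjusted p among those called, and up to 2 with the smallest p where few or none was called. It adds genes with a textbook tie to sarcoidosis, and MMP12 and ADAMDEC1, which the published study of these samples put forward. Because that study chose them on these samples, their results here are not independent evidence. Of the genes named in advance, 1 is not reported here.

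The fit was tested on simulated data with the real means and residual spread of the 19740 genes and 6 samples per group. It called 25 of 50 genes changed by 0.50 on the log2 scale, 47 of 50 changed by 1, 50 of 50 changed by 2 and 50 of 50 changed by 4, with 4 false calls among 19522 unchanged genes. The simulated noise was Gaussian and independent for each gene and array. Because it held no correlation between genes and no outlying array, these rates need not hold in the real data.

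Alternatives planned before the data were examined were leaving out the dimmest 40 percent of probe sets, quantile normalisation of the deposited values, subtraction of array medians, eBayes with trend and robust settings, array weights, the replicate number as a block, other choices of probe set per gene, surgical biopsies only, each array left out in turn, and an exact rank sum test. For lists they were an estimated correlation, the rotation test fry and the removal of genes shared between lists. Added after seeing the data were a fit with the 3' minus 5' difference of the actin control probe sets as a covariate, which reads RNA degradation, a fit with sarcoidosis replicates 2 to 5 only, and the 2 lists holding MMP12 or ADAMDEC1 without these genes.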

Results

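The data consist of 12 genome-wide expression profiles of human lung tissue, 6 from subjects with active pulmonary sarcoidosis, an inflammatory disease in which granulomas form in the lung, and 6 from subjects with normal lung anatomy. The series compares the groups to find genes expressed differently in the diseased lung. Array medians differed little between the groups (6.45 ± 0.03 in sarcoidosis and 6.46 ± 0.02 in normal lung, mean ± SD of log2 values, n = 6 each, two-sided exact permutation p = 0.431). Quantile normalisation makes array medians nearly equal, so they cannot show whether the groups were comparable before it. The actin 3' minus 5' difference, which grows as RNA degrades, was 2.42 ± 0.91 in sarcoidosis and 1.92 ± 0.71 in normal lung (exact permutation p = 0.305, and 0.534 after Benjamini-Hochberg adjustment over 7 array measures). The same difference for the GAPDH control probe sets was 1.29 ± 0.44 in sarcoidosis and 1.33 ± 0.35 in normal lung (exact permutation p = 0.883, adjusted 0.883). Only the actin difference was used as a covariate. The first principal component held 34.4% of the variance and its mean was 30.3 in sarcoidosis and -30.3 in normal lung (exact permutation p = 0.00866, adjusted 0.0606). Sarcoidosis replicate 6 stood apart at 123 on this component, and its mean correlation with its own group was 0.943, the lowest of the 12 arrays.

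Sarcoid lung differed from normal lung in 845 of 19740 genes, with 536 higher and 309 lower. Rises were larger than falls: 125 genes rose at least 2-fold and 15 fell at least 2-fold, and beyond 4-fold there were 10 rises and 1 fall. The groups did not overlap for 797 genes (4.04% of those tested, against 0.216% by chance), among them 395 of the genes that rose and 189 of those that fell. At an unadjusted p under 0.05 there were 4216 genes, and over all 54518 probe sets 1675 passed, 1088 higher and 587 lower. No called gene had another probe set called in the opposite direction. The count depended on single arrays. Without sarcoidosis replicate 5 there were 187 higher and 89 lower genes, without sarcoidosis replicate 3 there were 278 and 120, without normal replicate 2 there were 279 and 154, and without sarcoidosis replicate 4 there were 324 and 175. Without normal replicate 4 the lower genes numbered 155 and without normal replicate 3 they numbered 194, and without sarcoidosis replicate 5 the genes past 2-fold numbered 46 higher and 7 lower. Rises of at least 2-fold numbered 56 without normal replicate 2, 73 without sarcoidosis replicate 4, 75 without sarcoidosis replicate 3 and 78 without normal replicate 1. The exact rank sum test called no gene, since the smallest p of 6 against 6 samples, 0.00216, came to 0.0536 after adjustment. By that test 3740 genes had an unadjusted p under 0.05.

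**Figure D1:**
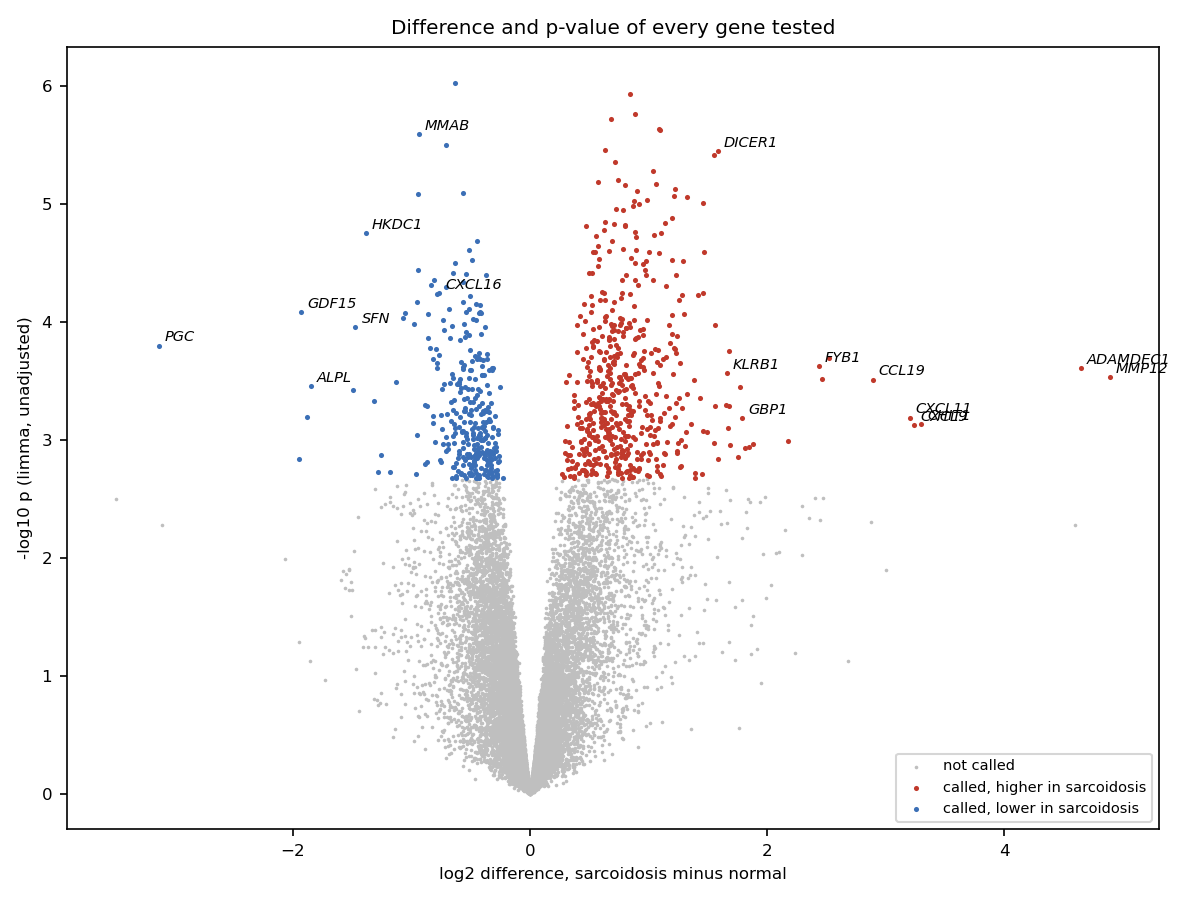
Each point is 1 of the 19740 genes, with the log2 difference between sarcoidosis and normal lung on the horizontal axis and -log10 of the unadjusted limma p on the vertical axis. Red points are the 536 genes that rose and blue points the 309 that fell, MMP12 and ADAMDEC1 lying farthest to the right and PGC farthest to the left among the called genes.

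The largest rises among called genes were those of MMP12 and ADAMDEC1, 2 members of the activated and granuloma macrophage list. Which cells of the tissue expressed them was not tested. MMP12, macrophage elastase, was 29.7-fold higher (log2 difference 4.89 ± 0.98, SE; 9.93 ± 2.62 in sarcoidosis and 5.04 ± 0.33 in normal lung, SD, n = 6 each, limma adjusted p = 0.0203). ADAMDEC1, a secreted metalloprotease-like protein of macrophages and dendritic cells, was higher by 4.65 ± 0.91 on the log2 scale (adjusted p = 0.0190). Both were chosen on these samples by the published study. CHIT1, a chitinase secreted by activated macrophages, was 9.87-fold higher (3.30 ± 0.74, adjusted p = 0.0296). These were the 3 of 21 measured genes of the activated and granuloma macrophage list that rose, and 11 rose adjusted over the list alone, a count that holds the 2 genes chosen on these samples. In all, 19 of the 21 were higher by any amount, with a median log2 difference of 1.11. The list stood above other genes by camera (adjusted p = 8.24e-07), with adjusted p = 0.725 with an estimated correlation, and its mean did not pass an exact permutation test after adjustment (p = 0.0152, adjusted 0.0823). Without MMP12 and ADAMDEC1, left out after the data were seen, 17 of 19 were higher by any amount, 1 rose over all genes and 5 adjusted over the list alone. The median was then 0.81, camera gave adjusted p = 2.45e-05, or adjusted p = 0.725 with an estimated correlation, and the exact permutation p of the mean was 0.0281 (adjusted 0.119). CYP27B1, the enzyme that makes active vitamin D, differed by 1.79 ± 0.69 (adjusted p = 0.156), or 1.17 without sarcoidosis replicate 6, and ACE by 0.40 ± 0.28 (adjusted p = 0.451), or 0.24 without sarcoidosis replicate 1 and 0.26 without normal replicate 1.

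The transbronchial sample did not share the rise of these macrophage genes, and it was also the lowest of the 12 arrays for the mean of the alveolar macrophage (-1.46), lysosome (-0.52) and complement lists (-0.87). In sarcoidosis replicate 1, MMP12 was at 5.42, ADAMDEC1 at 5.53 and CHIT1 at 7.07, inside the range of the normal arrays, while the other 5 sarcoidosis arrays lay between 8.71 and 12.20 for MMP12, between 9.65 and 12.69 for ADAMDEC1 and between 8.96 and 12.60 for CHIT1. Without this array, 9 of the 21 list genes rose and the MMP12 difference was 5.79 (adjusted p = 0.0034). Without sarcoidosis replicate 6 the count stayed at 3. Without sarcoidosis replicate 5 the adjusted p was 0.0525 for MMP12, 0.0524 for ADAMDEC1 and 0.0722 for CHIT1. The CHIT1 call was also lost without sarcoidosis replicate 4 or any of normal replicates 1, 2, 3, 4 and 6, within a range of 0.0112 to 0.0722. With the actin 3' minus 5' difference as a covariate the differences were 4.67 ± 1.06 for MMP12 and 3.20 ± 0.81 for CHIT1, with adjusted p of 0.0508 and 0.0696.

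**Figure D2:**
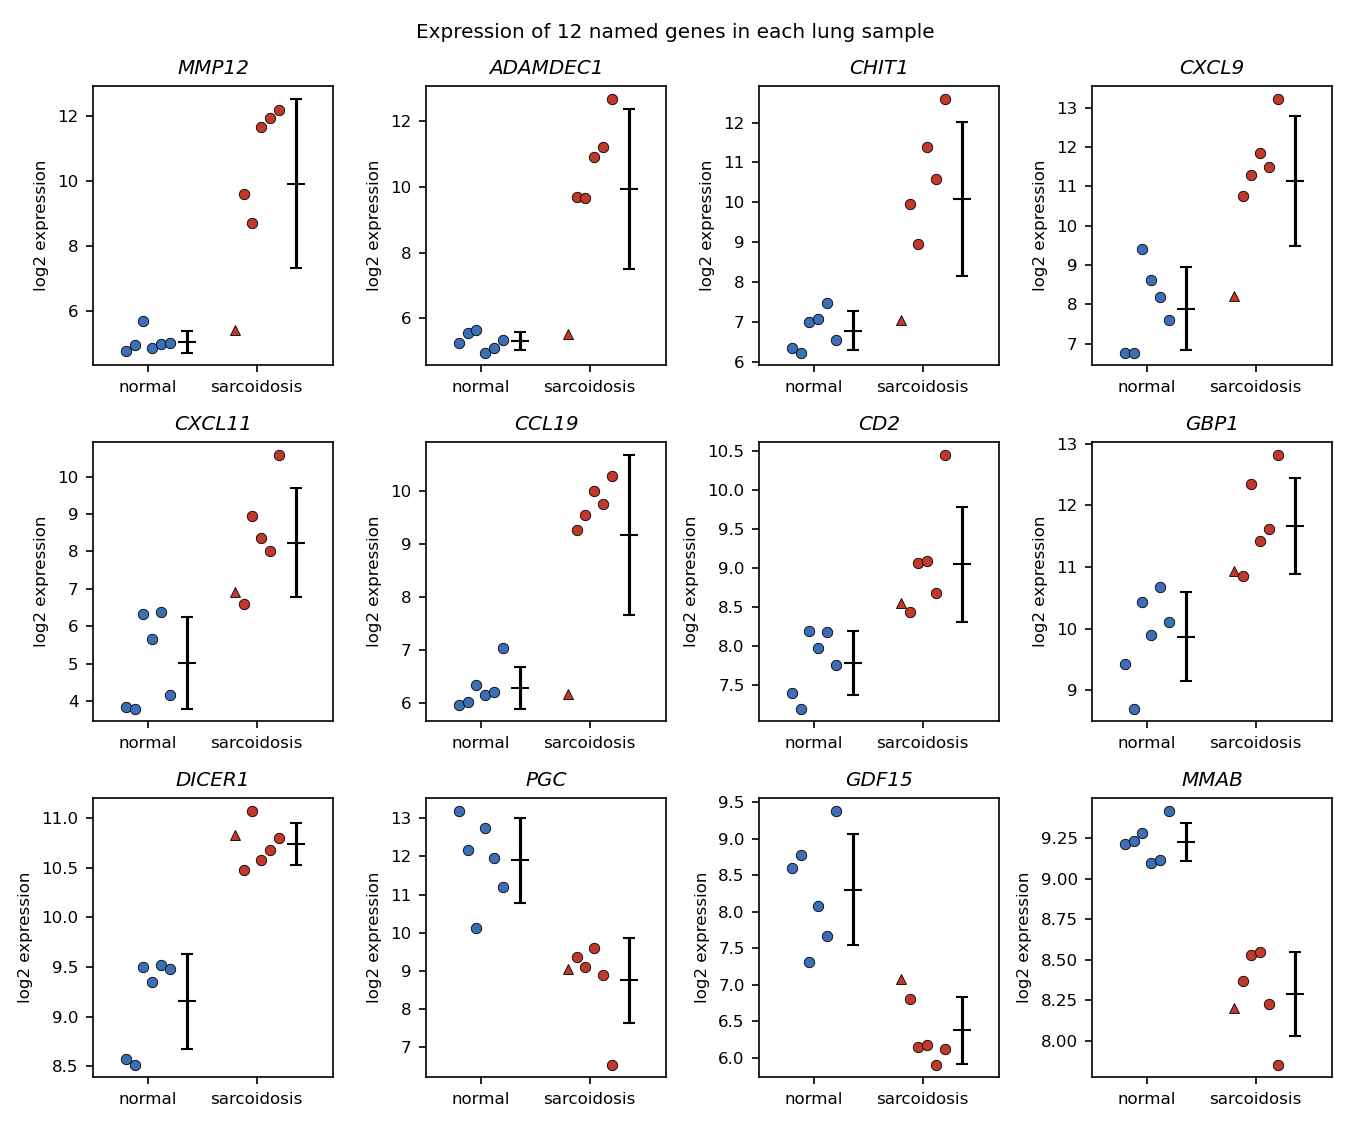
Log2 expression of 12 named genes in each of the 12 samples, 1 panel per gene, with normal lung in blue and sarcoidosis in red. Circles are surgical and the triangle is the transbronchial biopsy, and the bar at the right of each group is the mean with 1 SD. The triangle lies at the normal level for MMP12 (5.42), ADAMDEC1 (5.53), CHIT1 (7.07) and CCL19 (6.16), and with the other sarcoidosis samples for DICER1 (10.83).

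Of the 40 measured matrix metalloproteinases, ADAMs and TIMPs, 3 rose and none fell. Besides MMP12 and ADAMDEC1 this was ADAM9, a membrane-bound sheddase (0.47 ± 0.10, adjusted p = 0.0283). Adjusted over the list alone, 4 rose and 2 fell, the first count holding the genes chosen on these samples. The median difference of the list was 0.00 and its mean 0.39, and camera did not separate it from other genes (adjusted p = 0.398, or 0.813 with a mean of 0.16 without MMP12 and ADAMDEC1). ADAM9 turned to -0.25 (adjusted p = 0.469) when its probe set with the largest variance was used, to 0.08 (0.519) when its probe sets were averaged, and its call was lost without normal replicates 2 or 3 or sarcoidosis replicates 3, 4 or 5 (adjusted p up to 0.071) and with the actin covariate (0.44 ± 0.11, 0.0691).

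Of 26 measured genes induced by interferon-gamma, the main macrophage-activating cytokine of T cells, 10 rose and none fell, and 18 rose adjusted over the list alone. CXCL9 and CXCL11, chemokines that draw activated T cells, were 9.46-fold (3.24 ± 0.73, adjusted p = 0.0297) and 9.20-fold higher (3.20 ± 0.70, adjusted p = 0.0281). GBP1, an interferon-induced GTPase, was 3.47-fold higher (1.79 ± 0.40), GBP4 2.14-fold (1.10 ± 0.21) and TAP1, a subunit of the peptide transporter of antigen presentation, 2.40-fold (1.26 ± 0.26). BATF2, a transcription factor induced by interferon, was higher by 0.68 ± 0.14, and the adjusted p of these 4 genes ran from 0.0188 to 0.0283. CXCL10 differed by 2.35 ± 0.68 and did not pass (adjusted p = 0.0733), although it passed without the transbronchial sample (0.0365) and with array weights (0.0482). IFNG itself differed by 1.27 ± 0.45 (adjusted p = 0.130), and its level of 9.57 in sarcoidosis replicate 6 compared with 6.23 to 6.94 in the other 5. Without that array it differed by 0.79 (adjusted p = 0.0143), and it passed with array weights (0.0476). TNF differed by 0.38 ± 0.23 (adjusted p = 0.373), or 0.18 without sarcoidosis replicate 3.

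As a group the interferon-gamma genes had a median difference of 0.87 and were above other genes by camera (adjusted p = 1.08e-11), with adjusted p = 0.725 with an estimated correlation. The list mean was higher in all 6 sarcoidosis arrays than in any normal array (1.01 on average, exact permutation p = 0.00216, the smallest possible, adjusted 0.0274). Without sarcoidosis replicate 1 there were 12 genes that rose, without sarcoidosis replicate 6 there were 10, and without both there were 5. The calls of CXCL9 and CXCL11 were each lost without normal replicates 1, 2 or 6 or sarcoidosis replicates 3, 4 or 5, with adjusted p up to 0.0716 and 0.066. GBP1 was lost without normal replicates 1, 2 or 4 or sarcoidosis replicates 3 or 5 (up to 0.066), TAP1 without normal replicate 2 or sarcoidosis replicates 3 or 5 (up to 0.0562), and GBP4 and BATF2 without sarcoidosis replicate 5 (0.0514 and 0.0568). With the actin covariate 4 calls were lost, those of CXCL9 (2.93 ± 0.75, adjusted p = 0.0712), CXCL11 (93.6% of its difference kept, SE 0.75, 0.0691), GBP1 (1.53 ± 0.36, 0.0573) and TAP1 (1.21 ± 0.29, 0.0590). In the fit of sarcoidosis replicates 2 to 5 alone BATF2 was lost (0.0538). GBP1 (1.69) lay at the threshold there, passing (0.0492) with the probe sets chosen on all 12 arrays and not with those chosen on the arrays left. Of the 22 type I interferon genes, a family induced by viral sensing, none rose or fell, and IFIH1 (1.28 ± 0.40, adjusted p = 0.0935) and EPSTI1 (1.23 ± 0.40, adjusted p = 0.102) came closest. Their list had a median of 0.40 and a camera adjusted p of 0.0059, or adjusted p = 0.741 with an estimated correlation, and the call was lost without normal replicate 1 (median 0.16, adjusted p = 0.078).

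Of 19 T cell genes 18 were higher by any amount, 2 rose over all genes and 12 adjusted over the list alone. The 2 were CD2, an adhesion receptor (2.40-fold, 1.26 ± 0.32, adjusted p = 0.0450), and SH2D1A, a signalling adaptor (3.01-fold, 1.59 ± 0.39, adjusted p = 0.0406). Of 16 cytotoxic and natural killer cell genes all 16 were higher by any amount, and GZMA, granzyme A (3.68-fold, 1.88 ± 0.44, adjusted p = 0.0355), and KLRB1, a lectin-like receptor (3.16-fold, 1.66 ± 0.33, adjusted p = 0.0198), rose, or 4 adjusted over the list alone. The medians were 0.64 for T cells (camera adjusted p = 5.43e-07) and 0.87 for cytotoxic cells (5.00e-06), and for each adjusted p = 0.725 with an estimated correlation. The T cell mean was higher in every sarcoidosis array than in every normal array (difference 0.70, exact permutation p = 0.00216, adjusted 0.0274). The cytotoxic mean did not pass after adjustment (exact permutation p = 0.0130, adjusted 0.0823). Among 20 measured immunoglobulin and T cell receptor segment genes 1 rose, TRBC1 (1.27 ± 0.25, adjusted p = 0.0185), which is named here after its value was seen.

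Sarcoidosis replicate 6 had a T cell list mean of 1.78, against 0.37 to 0.67 in the other 5 sarcoidosis arrays. Without it the T cell median was 0.42 and 5 members rose, and of the cytotoxic genes 1 rose. Without the transbronchial sample 2 T cell genes and 1 cytotoxic gene rose. The calls of CD2, SH2D1A and GZMA were each lost in the actin covariate fit (adjusted p = 0.101, 0.095 and 0.086), where CD2 differed by 1.20 ± 0.34 and GZMA by 1.75 ± 0.47, and SH2D1A kept 94.2% of its difference with an SE of 0.42. They were also lost without sarcoidosis replicates 3, 4 or 5 or normal replicates 1, 2, 3, 4 or 6. CD2 was also lost without normal replicate 5, SH2D1A without sarcoidosis replicates 1 or 2, and GZMA without sarcoidosis replicates 1 or 6, with adjusted p up to 0.0954, 0.0888 and 0.0735. Averaged over its 4 probe sets SH2D1A differed by 0.59 (adjusted p = 0.0999). KLRB1 was lost with sarcoidosis replicates 2 to 5 only (0.0636).

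T cell subsets were less clear at the level of single genes. None of the 17 Th1, 9 Th2, 9 Th17 or 9 regulatory T cell genes rose or fell. Closest were STAT4 (0.66 ± 0.19, adjusted p = 0.0762) and TBX21 (0.52 ± 0.18, 0.116) for Th1, GATA3 (0.74 ± 0.23, 0.0967) and CCR4 (0.17 ± 0.07, 0.175) for Th2, CCR6 (0.62 ± 0.29, 0.241) and IL23R (0.23 ± 0.11, 0.278) for Th17, and TIGIT (0.44 ± 0.12, 0.0606) and IKZF2 (0.95 ± 0.31, 0.102) for regulatory cells, each a log2 difference with its adjusted p. TIGIT passed without sarcoidosis replicate 1 (0.0468) and with array weights (0.0324), and IKZF2 without normal replicate 5 (0.0366), while CCR6 differed by 0.36 without sarcoidosis replicate 6. List medians were 0.13, 0.00, 0.23 and 0.26, and over the 12 fits that left out 1 array they ran from 0.06 to 0.19, from -0.05 to 0.02, from 0.09 to 0.27 and from 0.04 to 0.33. The lowest Th1 and regulatory medians came without sarcoidosis replicate 6 and the lowest Th17 median without sarcoidosis replicate 3. By camera the Th1 list (adjusted p = 0.0230, or adjusted p = 0.741 with an estimated correlation) and the regulatory list (0.0253, or adjusted p = 0.725 with an estimated correlation) stood above other genes, and both were lost without sarcoidosis replicate 6 (adjusted p = 0.0879 and 0.0949). The regulatory list was also lost without normal replicate 2 (0.0573), without dim probe sets (0.136) and with the actin covariate (0.0516), and the Th1 list with array weights (0.0640) and with sarcoidosis replicates 2 to 5 only (median 0.04, adjusted p = 0.0917). Adjusted over the list alone, 2 regulatory genes rose and none in the other subsets.

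Chemokines moved both ways. Of 30 measured genes 4 rose and 1 fell, or 8 and 1 adjusted over the list alone. CCL19, which guides T cells and dendritic cells into lymphoid tissue, was 7.42-fold higher (2.89 ± 0.58, adjusted p = 0.0205) beside CXCL9, CXCL11 and CCL5 (1.46 ± 0.33, adjusted p = 0.0315), the last named after its value was seen. CXCL16, a membrane-bound chemokine made by macrophages and epithelium, was lower (log2 difference -0.76 ± 0.13, adjusted p = 0.0125). The list median was 0.32 (camera adjusted p = 0.0139, or adjusted p = 0.725 with an estimated correlation). Without sarcoidosis replicate 1 there were 6 that rose, without sarcoidosis replicate 6 there were 3, and camera lost the list without sarcoidosis replicate 3 (median 0.12, adjusted p = 0.0879), without genes shared between lists (0.271) and with the actin covariate (0.0829). CCL19 was at 6.16 in the transbronchial sample and between 9.26 and 10.28 in the other 5 sarcoidosis samples, and its call was lost without sarcoidosis replicate 5 (adjusted p = 0.0556).

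CCL19 was also the 1 of 12 lymphoid organisation genes that rose, with 3 adjusted over the list alone, and LTB (1.31 ± 0.40, adjusted p = 0.0851) and TNFSF13B, the B cell survival factor BAFF (1.79 ± 0.55, adjusted p = 0.0870), came next. TNFSF13B passed without the transbronchial sample (2.18, adjusted p = 0.0288), and LTB with array weights (0.0423). That list had a median of 0.75 and a camera adjusted p of 0.0113, with adjusted p = 0.725 with an estimated correlation. Without genes shared between lists its call was lost (median 1.31, adjusted p = 0.192). None of 14 B cell genes rose or fell (median 0.11, camera adjusted p = 0.108), although the list passed camera without sarcoidosis replicate 3 (0.0490) or 5 (0.0290) and with the actin covariate (0.0327). With an estimated correlation these gave adjusted p = 0.719, 0.652 and 0.760. FCRLA was at 0.39 ± 0.15 (adjusted p = 0.162) and SPIB at 0.59 ± 0.28 (0.244), or 0.35 without sarcoidosis replicate 6. The B cell median was 0.04 without normal replicate 3, 0.06 without sarcoidosis replicate 4 and 0.07 without sarcoidosis replicate 6. None of 12 plasma cell genes did either (median 0.16, or -0.07 without sarcoidosis replicate 6, camera adjusted p = 0.561). SLAMF7, shared by plasma and cytotoxic cells, differed by 2.40 ± 0.65 (adjusted p = 0.0602), and passed without the transbronchial sample (2.81, 0.0285), with array weights (0.0237) and without dim probe sets (0.0496), and PRDM1 by 1.13 ± 0.39 (0.119), and 1 plasma cell gene rose adjusted over the list alone.

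Of 13 alveolar type 2 cell genes, those of the surfactant-making cells, all 13 were lower by any amount, 1 fell over all genes and 4 adjusted over the list alone. PGC, a protease precursor of these cells in the lung, was 8.78-fold lower (-3.13 ± 0.58, adjusted p = 0.0169), the largest fall of any called gene. SLC34A2, a phosphate transporter, differed by -1.24 ± 0.42 (adjusted p = 0.112) and LPCAT1, an enzyme of surfactant lipid synthesis, by -1.02 ± 0.34 (0.114). Both passed without sarcoidosis replicate 6, at smaller differences (SLC34A2 -0.83, adjusted p = 0.0373, and LPCAT1 -0.67, 0.0237), and LPCAT1 with array weights (0.0481). The list median was -1.08 (camera adjusted p = 0.000145, or adjusted p = 0.725 with an estimated correlation), and the list mean was lower in all 6 sarcoidosis arrays than in any normal array (exact permutation p = 0.00216, adjusted 0.0274). Sarcoidosis replicate 6 had a list mean of -3.77, against -0.89 to -0.34 in the other 5. Without it the median was -0.50 and 5 genes fell, and without the transbronchial sample the median was -1.03 and 1 gene fell.

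In the lists of other structural cells of the lung, no member rose or fell among 13 alveolar type 1 genes (median -0.42), 12 ciliated cell genes (0.06), 15 airway secretory, basal and gland genes (median -0.04 but mean 0.27), 18 endothelial genes (-0.12), 8 lymphatic vessel genes (-0.05), 22 collagen and matrix genes (0.11), 14 fibroblast and smooth muscle genes (-0.31) or 10 mesothelium and cartilage genes (-0.21), with camera adjusted p from 0.233 to 0.951. Camera gave the endothelial list a positive direction although its median and mean were negative. Without sarcoidosis replicate 6 its median was 0.31 and it passed camera (adjusted p = 0.0098, or adjusted p = 0.779 with an estimated correlation), as it did with array weights (0.0397, or adjusted p = 0.777 with an estimated correlation). Single arrays set the sign of most of these medians. Without sarcoidosis replicate 6 the median was 0.21 for alveolar type 1 genes, 0.26 for airway genes, 0.09 for lymphatic vessels and -0.03 for fibroblasts, and without normal replicate 1 it was 0.05 for fibroblasts. Over the 12 fits that left out 1 array the medians ran from -0.65 to 0.21 for alveolar type 1, from -0.19 to 0.37 for ciliated, from -0.20 to 0.26 for airway, from -0.36 to 0.31 for endothelial, from -0.12 to 0.09 for lymphatic, from -0.10 to 0.36 for matrix and from -0.46 to 0.05 for fibroblast genes. For mesothelium and cartilage genes they ran from -0.28 to -0.12. The matrix list passed camera without normal replicate 1 (adjusted p = 0.0178) and with array weights (0.00845), or with an estimated correlation adjusted p = 0.762 and 0.777. The 2 genes with the smallest p were GPRC5A (-0.89 ± 0.67) and HOPX (-0.64 ± 0.47) for alveolar type 1, ARMC3 (0.35 ± 0.46) and TPPP3 (-0.43 ± 0.55) for ciliated, LTF (1.99 ± 0.76) and PIGR (-0.84 ± 0.42) for airway and gland cells, FLT1 (0.51 ± 0.22) and IL7R (0.91 ± 0.46), which T cells also express, for endothelium, CCL21 (-0.59 ± 0.36) and RELN (0.14 ± 0.15) for lymphatics, POSTN (1.68 ± 0.78) and FN1 (0.31 ± 0.15) for matrix, LUM (0.53 ± 0.21) and DCN (0.26 ± 0.14) for fibroblasts, and CALB2 (-0.49 ± 0.32) and SOX9 (-0.29 ± 0.17) for mesothelium and cartilage, with adjusted p of 0.154 or more. Without sarcoidosis replicate 6 GPRC5A was at -0.17, HOPX at -0.18, PIGR at -0.44, TPPP3 at -0.02 and ARMC3 at 0.53, and without normal replicate 3 ARMC3 was at 0.73 and TPPP3 at -0.15. TPPP3 was at -0.28 without normal replicate 4 and -0.66 without sarcoidosis replicate 1, and ARMC3 at 0.16, 0.19 and 0.15 without normal replicate 6 and sarcoidosis replicates 1 and 4. CCL21 was at -0.38 without sarcoidosis replicate 3, RELN at 0.03 and 0.07 without sarcoidosis replicate 2 and normal replicate 6, and LUM, CALB2 and SOX9 at 0.34, -0.16 and -0.12 without normal replicate 2. FLT1 passed with array weights (0.0379).

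**Figure D3:**
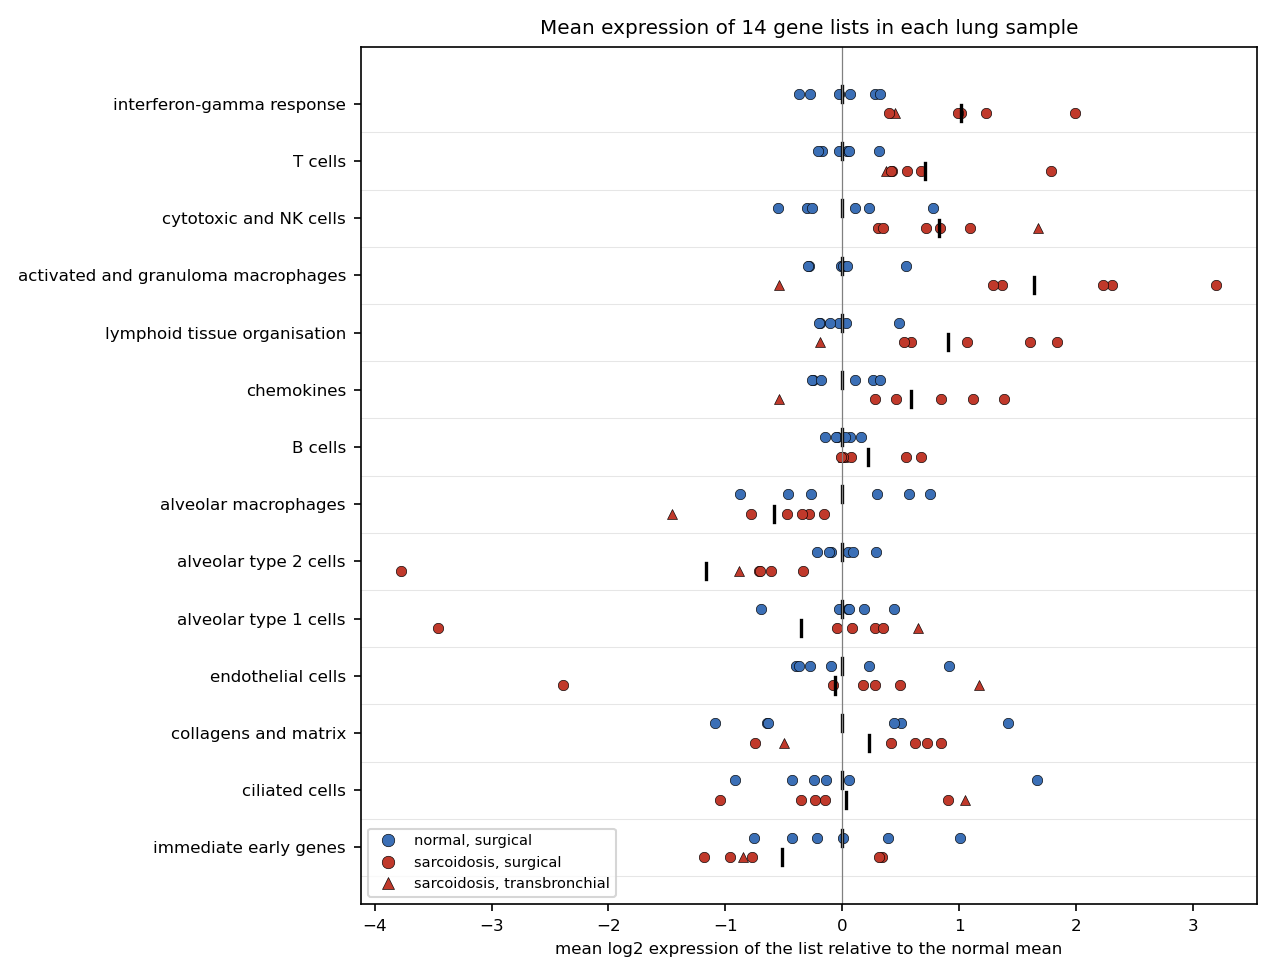
Mean log2 expression of 14 gene lists in each sample, relative to the mean of the normal samples, on the horizontal axis, with normal lung in blue, surgical sarcoidosis samples as red circles, the transbronchial sample as a red triangle and group means as black bars. Interferon-gamma, T cell and alveolar type 2 lists separate the groups, and 1 sarcoidosis sample lies at -3.77, -3.46 and -2.39 for alveolar type 2, alveolar type 1 and endothelial genes.

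Other myeloid lists were mixed. Of 17 alveolar macrophage genes 13 were lower by any amount and none fell over all genes, or 1 adjusted over the list alone, with ALOX5AP at -1.13 ± 0.30 (adjusted p = 0.0541) and VSIG4 at -0.95 ± 0.30 (0.0974). ALOX5AP passed without sarcoidosis replicate 6 (0.0454) or normal replicate 1 (0.0360), without dim probe sets (0.0442), with array weights (0.0102) and with the probe set of largest variance (0.0485). The alveolar macrophage median was -0.49 (-0.33 without sarcoidosis replicate 1 and -0.82 without normal replicate 1) and camera placed the list below other genes (adjusted p = 0.0139, or adjusted p = 0.741 with an estimated correlation), a call lost without sarcoidosis replicate 1 or normal replicates 5 or 6 (up to 0.110) and with sarcoidosis replicates 2 to 5 only (-0.41, 0.0917). Of 20 lysosome genes GAA, acid alpha-glucosidase, fell (-0.76 ± 0.19, adjusted p = 0.0421), or 4 fell and 1 rose adjusted over the list alone, and HEXA (-0.39 ± 0.11, 0.0674) and CTSD (-0.45 ± 0.14, 0.0897) came next. HEXA passed without sarcoidosis replicate 6 (0.0481) and with array weights (0.0290), and CTSD without sarcoidosis replicate 4 (0.0350). Of 16 neutrophil genes CSF3R, the G-CSF receptor, fell (-0.65 ± 0.16, adjusted p = 0.0449), with VNN2 at 0.68 ± 0.34 and CXCR1 at -0.15 ± 0.09. The calls of GAA and CSF3R were lost in 10 and 9 of the 12 fits that left out 1 array, with adjusted p up to 0.101 without sarcoidosis replicate 5 for GAA and 0.105 without the same array for CSF3R. With the actin covariate GAA was at -0.68 ± 0.19 (0.0984) and CSF3R at -0.66 ± 0.18 (0.0845), and both calls were also lost with surgical biopsies only (0.0631 and 0.0548), with trend and robust settings (0.0502 and 0.0557) and with averaged probe sets (0.0521 and 0.0531), and CSF3R after quantile normalisation (0.0511). None of 15 dendritic cell, 8 mast cell, 7 erythroid or 12 MHC class II genes rose or fell. By camera the dendritic (median 0.16, adjusted p = 0.0412, or adjusted p = 0.725 with an estimated correlation) and MHC class II lists (0.28, 0.0475, or adjusted p = 0.741 with an estimated correlation) stood above other genes. Their leading members were CLEC10A (1.15 ± 0.37), CCR7 (0.84 ± 0.32), HLA-DOB (0.63 ± 0.28) and HLA-DOA (0.59 ± 0.30). CLEC10A passed without the transbronchial sample (1.44, adjusted p = 0.0220) and with array weights (0.0491). The MHC class II median ran from 0.11 without normal replicate 1 to 0.39 over the 12 fits that left out 1 array. The dendritic call was lost without normal replicates 1, 2 or 4 or sarcoidosis replicates 3, 4 or 6 (up to 0.112), and the MHC class II call without normal replicates 1, 2 or 5 or sarcoidosis replicates 4 or 6 (up to 0.290). Without genes shared between lists the dendritic call (0.151) and the MHC class II call (0.0955) were lost, as they were with the actin covariate (0.0964 and 0.133), and the MHC class II call also ended with array weights (0.174), after subtraction of array medians (0.0539) and without dim probe sets (0.0511). The mast cell list (median -0.38, with HPGDS at -0.96 ± 0.41 and SLC18A2 at -0.69 ± 0.29) and the erythroid list (0.03, with EPB42 at 0.08 ± 0.12 and HBD at 0.19 ± 0.30, or 0.01 and -0.05 without sarcoidosis replicate 1) did not pass (camera adjusted p = 0.153 and 0.806), although the mast cell list did without sarcoidosis replicate 2 (0.0478) or 4 (0.0379), with adjusted p = 0.625 and 0.645 with an estimated correlation, and HPGDS passed with array weights (0.0495).

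Among pathways of cell state, oxidative phosphorylation had 1 of 23 genes that rose, SDHD, a subunit of succinate dehydrogenase (0.85 ± 0.19, adjusted p = 0.0273), beside SDHA of the same complex at -0.35 ± 0.11 (0.0893) and NDUFB5 at 0.53 ± 0.18 (0.115), and its list median was -0.05. The SDHD call was lost without normal replicates 2 or 3 or sarcoidosis replicates 3, 4 or 5 (up to 0.0686), and with the actin covariate (0.80 ± 0.20, 0.0679), and its difference was 0.52 when its probe sets were averaged. SDHA passed without normal replicate 6 (0.0410). No member rose or fell among 20 proliferation genes (median -0.01, mean 0.13, CCNA2 0.67 ± 0.21, PCNA 0.45 ± 0.16), 15 hypoxia genes (0.13, EGLN3 0.85 ± 0.33 or 0.56 without sarcoidosis replicate 6, SLC2A1 0.41 ± 0.15), 17 glycolysis genes (-0.13, ENO2 -0.59 ± 0.18, ALDOC -0.33 ± 0.10), 10 heat shock genes (-0.05, HSPH1 0.60 ± 0.23, HSPA6 0.94 ± 0.42 or 0.54 without sarcoidosis replicate 6) or 9 vitamin D and calcium genes (median -0.06, mean 0.19, CYP27A1 -0.31 ± 0.13). None of these lists passed camera (adjusted p from 0.382 to 0.996). Over the 12 fits that left out 1 array, medians ran from -0.07 to 0.10 for proliferation and from -0.06 to 0.16 for hypoxia. They ran from -0.18 to -0.02 for glycolysis and from -0.11 to 0.06 for heat shock. For vitamin D and calcium they ran from -0.10 to 0.07, and for oxidative phosphorylation from -0.13 to -0.004. Immediate early genes, which are induced within minutes of tissue handling or stimulation, were lower in 24 of 25 members with none past the test, NR4A1 at -1.03 ± 0.37 (0.135) and CCN1 at -0.94 ± 0.31 (0.112). Their list had a median of -0.50 and camera adjusted p = 0.0139, or adjusted p = 0.741 with an estimated correlation, and lost the call without normal replicate 6 (0.216) or sarcoidosis replicate 6 (median -0.33, adjusted p = 0.102). Complement genes had a median of -0.40 with C2 at -0.40 ± 0.14 and CFI at -0.67 ± 0.26, which passed with the probe set of largest variance (-0.76, 0.0265, and -1.04, 0.0309), and camera adjusted p = 0.0499, or adjusted p = 0.725 with an estimated correlation. The complement median was -0.26 without sarcoidosis replicate 1 and -0.23 without sarcoidosis replicate 6. With sarcoidosis replicates 2 to 5 only both lists were lost, with medians of -0.27 for immediate early and -0.13 for complement genes (adjusted p = 0.275 for each). The complement call was lost without normal replicates 1, 2, 4 or 6 or sarcoidosis replicates 1, 2 or 6 (up to 0.177), without genes shared between lists (0.0949), without dim probe sets (0.101) and with array weights (0.201).

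The largest rises among genes whose groups did not overlap held further genes outside the lists. FYB1, an adaptor of T cell receptor signalling, was 5.41-fold higher (2.44 ± 0.47, adjusted p = 0.0188). CD48, a lymphocyte adhesion receptor, was 3.21-fold higher, BCL11B, a T cell transcription factor, 3.14-fold, WIPF1, a partner of the Wiskott-Aldrich protein, 2.94-fold, LY75, an endocytic receptor of dendritic cells, 3.18-fold, and ST8SIA4, a polysialyltransferase, 3.20-fold. ZNF267 was 3.61-fold higher, HS3ST3B1, a heparan sulfate sulfotransferase, 3.51-fold, RUNX2, a transcription factor of bone, 3.42-fold, and SGTB, a co-chaperone, 2.95-fold. DICER1, the nuclease that makes microRNAs, was higher by 1.58 ± 0.20 on the log2 scale (10.74 ± 0.21 in sarcoidosis and 9.16 ± 0.48 in normal lung, adjusted p = 0.00695). The adjusted p of these 11 genes lay between 0.00695 and 0.0372. Of the 6 probe sets of DICER1, 2 passed the test in this direction, as did 1 of 6 for RUNX2, 3 of 5 for FYB1 and 1 of 3 for BCL11B. Averaged over all probe sets of the gene the difference was smaller by over 1.5 times for DICER1 (0.57), FYB1 (1.59), SGTB (0.86) and ST8SIA4 (0.97), and the call was lost for RUNX2 (0.31), HS3ST3B1 (0.61), WIPF1 (0.74) and BCL11B (0.88), with adjusted p from 0.0531 to 0.0908. BCL11B, WIPF1 and RUNX2 were highest in sarcoidosis replicate 6 (9.47, 11.10 and 9.93), far above the other 5 sarcoidosis arrays. With the actin covariate BCL11B (1.64 ± 0.39, 0.0588), CD48 (1.56 ± 0.38, 0.0639), HS3ST3B1 (1.74 ± 0.47, 0.0860), LY75 (1.59 ± 0.41, 0.0733), RUNX2 (1.68 ± 0.39, 0.0551), WIPF1 (1.46 ± 0.36, 0.0639) and ZNF267 (1.64 ± 0.44, 0.0855) missed the threshold, against 1.65 ± 0.35, 1.68 ± 0.36, 1.81 ± 0.43, 1.67 ± 0.38, 1.77 ± 0.36, 1.56 ± 0.33 and 1.85 ± 0.44 without it.

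PGC was 1 of the 15 largest falls named among genes whose groups did not overlap. Of the other 14, GDF15, a stress-induced cytokine, was 3.81-fold lower (-1.93 ± 0.33, adjusted p = 0.0143). GLDN, gliomedin, was 3.68-fold lower, ALPL, tissue-nonspecific alkaline phosphatase, 3.61-fold, SFN, the epithelial 14-3-3 sigma protein, 2.78-fold, and HKDC1, a hexokinase, 2.61-fold. LINC02615, a noncoding RNA, was 2.11-fold lower, ZNF431 2.08-fold, HOOK2 1.97-fold, CLDN7, a tight junction claudin, 1.94-fold, ASNS, asparagine synthetase, 1.94-fold, CA5BP1, a carbonic anhydrase pseudogene, 1.93-fold, QSOX1, a sulfhydryl oxidase, 1.92-fold and EPB41L1, a membrane cytoskeleton protein, 1.85-fold. MMAB, an enzyme of cobalamin metabolism, was 1.92-fold lower with the smallest adjusted p of these (-0.94 ± 0.11, adjusted p = 0.00695). The adjusted p of the others lay between 0.00731 and 0.0432. Averaged over all probe sets of the gene the difference was smaller by over 1.5 times for GDF15 (-0.82, 1 of 3 probe sets called), HKDC1 (-0.49, 1 of 4), GLDN (-1.04), ALPL (-1.19) and CA5BP1 (-0.59), and the call was lost for ZNF431 (-0.50), ASNS (-0.47), QSOX1 (-0.62) and EPB41L1 (-0.27), with adjusted p from 0.0699 to 0.132. With the actin covariate ALPL (-1.78 ± 0.41, 0.0539), ASNS (-0.85 ± 0.22, 0.0766) and EPB41L1 (-0.80 ± 0.23, 0.101) missed the threshold, against -1.85 ± 0.38, -0.96 ± 0.22 and -0.89 ± 0.22 without it. QSOX1 was lost with the probe set of largest variance (-0.67, 0.151).

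Of the 45 genes named in the text by the rule that passed the test, 17 kept their call in each of the 12 fits that left out 1 array. They were KLRB1, FYB1, DICER1, ST8SIA4 and SGTB among the rises, and CXCL16, PGC, GDF15, SFN, HKDC1, LINC02615, ZNF431, HOOK2, CLDN7, CA5BP1, QSOX1 and MMAB among the falls. Of the 45, calls were lost for 28 without sarcoidosis replicate 5, for 20 without normal replicate 2, for 17 and 16 without sarcoidosis replicates 3 and 4, for 14, 10, 12, 2 and 12 without normal replicates 1, 3, 4, 5 and 6, and for 4, 4 and 3 without sarcoidosis replicates 1, 2 and 6. With the actin 3' minus 5' difference as a covariate 22 of the 45 passed. The other 23 kept 85.2% to 102% of their difference, each moving by at most 0.741 of its SE, and their SEs were 90.8% to 110% of the earlier ones, with a median of 107%. In that fit 386 genes passed in place of 845, which makes the adjustment stricter. The calls therefore ended without a loss of most of the difference. When all probe sets of a gene were averaged 32 of the 45 passed. With sarcoidosis replicates 2 to 5 only 33 of the 45 passed. ADAM9, ASNS, BATF2, CSF3R, GAA, GBP1, GLDN, GZMA, KLRB1, LY75, SDHD and SH2D1A were lost, GBP1 only where probe sets were chosen again on the arrays left.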

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

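The tests of the transbronchial and the sarcoidosis replicate 6 patterns were chosen after those results were seen, and the counts over other splits were planned before. The lymph node test first asked only whether the B cell mean exceeded every other array, which would have argued against it, and the bound was moved to the normal arrays after its value was seen. Results are given here where 1 sample lay far from the other 5 of its group, with a gap of more than 0.625 of the group's range (Dixon's criterion). Of 312 groups of 6 values examined, 38 met it, where chance gives about 1 in 20, or 15.6. The groups are not independent, since list means and genes of the same lists were examined on the same arrays. The 38 therefore cannot be read as separate results or as a measured excess over 15.6. Sarcoidosis replicate 6 accounts for 20 of them.

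Among list means, relative to the normal mean, sarcoidosis replicate 6 was far out for T cells (1.78), alveolar type 2 cells (-3.77), alveolar type 1 cells (-3.46) and endothelial cells (-2.39). Among single genes it was far above its group for BCL11B (9.47), CCR4 (6.65), CD2 (10.45), HSPA6 (11.14), IFNG (9.57), RUNX2 (9.93), SH2D1A (8.79) and WIPF1 (11.10). It was far below for EPB41L1 (5.51), GPRC5A (7.72), HOOK2 (7.23), HOPX (9.84), LPCAT1 (9.90), PGC (6.55), PIGR (9.44) and SLC34A2 (8.80). The transbronchial sample was far below the other sarcoidosis samples for CCL19 (6.16) and VSIG4 (9.40). Sarcoidosis replicate 2 was high for RELN (7.41), and sarcoidosis replicate 3 for the neutrophil list mean (1.38).

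Among normal samples, replicate 2 had high list means for mesothelium and cartilage (1.10), heat shock (0.17) and glycolysis (0.27), high CALB2 (7.63) and SOX9 (8.44), and low CCR7 (6.23) and LUM (11.21). Normal replicate 3 was high for the airway secretory, basal and gland list (1.85), for ARMC3 (8.57), a ciliated cell gene, and for MMP12 (5.69). Normal replicate 6 was high for lymphoid organisation (0.49) and CCL19 (7.02), normal replicate 1 for hypoxia (0.32) and normal replicate 5 for regulatory T cells (0.24).

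The low alveolar and endothelial genes of sarcoidosis replicate 6 were weighed first. Its actin 3' minus 5' difference of 2.30 lay inside the range of the other 11 arrays, 0.667 to 3.63, which argues against degraded RNA on this array. Lymph node tissue in the sample cannot be told apart: its B cell mean of 0.54 was -0.13 relative to sarcoidosis replicate 4 but above the other 10 arrays (0.16 or less), and it was the highest of the 12 for T cells (1.78), lymphoid organisation (1.83) and plasma cells (1.23). A smaller share of alveolar tissue cannot be told apart either, since its being lowest for 40 of 44 alveolar type 1, alveolar type 2 and endothelial genes (90.91%) restates the pattern. No other biological explanation was tested.

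The macrophage genes at the normal level in the transbronchial sample were weighed next. A normal sample carrying the wrong label could give such values, but over the 758 genes outside the lists that passed without this array, its median position was 0.693 on a scale from the normal mean (0) to the mean of the other sarcoidosis arrays (1). Surgical sarcoidosis arrays, each left out in turn, lay between 0.674 and 1.26 on that scale and normal arrays between -0.29 and 0.36, which argues against that explanation for these genes. Measures over the whole array were less clear. On the first principal component this array was at -21.3, inside the normal range of -67.3 to -0.43, with the other sarcoidosis arrays at 4.62 or more. Its mean correlation was 0.964 with its own group and 0.966 with the normal group. For sarcoidosis replicate 2 these were 0.974 and 0.975. The 9 genes of the granuloma macrophage list that passed without sarcoidosis replicate 1 had a median position of -0.16, and 12 interferon-gamma genes had 0.549. Biopsy type cannot be told apart from the person sampled, since there was only 1 transbronchial array. A sample that missed granulomas is an untested biological explanation.

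Chance as the source of the gene counts was examined with 100 of the 462 splits of the 12 arrays into 6 and 6, the real one included. The real split was the only 1 of the 100 that called as many genes (845, highest other 1) and probe sets (1675, highest other 1). The same held for genes changed at least 2-fold (140, highest other 0). The 536 higher and 309 lower genes were each set against the larger direction of every other split, which held at most 1 gene. Chance is therefore an unlikely source of these counts, but 100 splits cannot show a share below 1 in 100. Splits that mix the groups also carry the real difference in their residual spread, which lowers their counts. For the 15 gene lists called by camera with its preset correlation, chance cannot be excluded: 41 of the 100 splits called as many, and the highest other called 27.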

How the results depend on the processing

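The actin covariate, the fit without sarcoidosis replicates 1 and 6, the lists without MMP12 and ADAMDEC1 (15 called) and the permutation of list means were chosen after seeing the data. Where a count moved by over 1.5 times, the cause was not tested unless stated. Against 536 higher, 309 lower, 125 and 15 genes past 2-fold, 1675 probe sets and 15 lists, eBayes with trend and robust settings gave 201 lower genes, and array weights gave 849 higher, 638 lower, 33 lower at least 2-fold and 2688 probe sets. The mean of all probe sets of a gene gave 275 higher and 41 at least 2-fold higher, and the probe set with the largest variance gave 199 at least 2-fold higher and 33 lower. The actin 3' minus 5' covariate gave 256 higher, 130 lower, 58 at least 2-fold higher and 602 probe sets. Sarcoidosis arrays 2 to 5 only, with fewer samples, gave 141 lower, 8 at least 2-fold lower and 830 probe sets. The exact rank sum test gave 0 genes in every count and 0 probe sets, since its smallest p is 0.00216. Camera with an estimated correlation called 0 lists, fry 0 (8 with its mixed test), and exact permutation of list means 3. Leaving out genes shared between lists called 10.

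Leaving out 1 array at a time gave 187 to 552 higher and 89 to 299 lower genes, 46 to 163 at least 2-fold higher and 7 to 22 at least 2-fold lower, 455 to 1543 probe sets and 10 to 16 lists. The lowest gene and probe set counts came without sarcoidosis replicate 5 (187, 89, 46, 7 and 455) and the lowest list count without sarcoidosis replicate 6. Quantile normalisation, subtraction of array medians, the filter on dim probe sets and surgical biopsies only kept each count within 1.5 times. Of the 845 genes called, 793 were also called after quantile normalisation, 800 after subtraction of medians, 635 with surgical biopsies only, 371 with the actin covariate and 274 without sarcoidosis replicate 5. The share of called genes that were higher was 63.4% in the main fit and 57.1% with array weights. Over the settings that called any gene it ran from 54.8% with all probe sets averaged to 72.8% with sarcoidosis replicates 2 to 5 only.

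The replicate numbers were not taken as pairs: the residual correlation of samples with the same number was 0.170, 0.050, -0.139, -0.010, -0.072 and 0.001, and 1 of 6 normal samples correlated best with the sarcoidosis sample of its own number. A fit with the replicate block called 444 higher and 182 lower genes and 1076 probe sets, sharing 475 genes with the 845. Of the 45 named genes called, 35 kept their call with it.

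Among called results, 1 reversed: ADAM9 was -0.25 with the probe set of largest variance, since another probe set was used. Results not called in either setting changed sign 80 times for lists and 5 times for genes, and these were not counted as reversals, a rule set after they were seen. Signal over background limits dim genes such as MMP12 in normal lung (5.04), below the array medians.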

Other observations

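The tests of the zinc finger and sterol families below used gene families chosen after the gene table was seen, and the covariate tests were written before their values were seen. As first written they asked only whether the median stayed above 0.75 of its unadjusted value, and by that rule all 3 covariates would have been argued against. The condition that it do so by more than its jackknife SE was added after the first values were seen, and with it none of the 3 is settled. The unadjusted medians of both families miss that condition too. It therefore could not argue against a covariate that changed neither the median nor its SE.

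Of 20 measured genes of cholesterol synthesis and its regulation, a list written after the called genes were seen, 6 fell and none rose. Because these data prompted the list, no p-value is given for it. The 6 were FDPS (-0.82 ± 0.16, adjusted p = 0.0180), EBP (-0.87 ± 0.19, 0.0255), TM7SF2 (-0.77 ± 0.15, 0.0178), MVD (-0.52 ± 0.09, 0.0140), ERG28 (-0.88 ± 0.19, 0.0253) and MMAB (-0.94 ± 0.11, 0.00695), which is a cobalamin enzyme and no member of the pathway. Without MMAB and the genes of uptake, regulation and transport, 5 of 16 fell, with a median difference of -0.58 (-0.58 after quantile normalisation and -0.56 after subtraction of array medians). A smaller share of alveolar type 2 cells, which make surfactant lipid, may account for it. With the alveolar type 2 mean as a covariate the median difference of the 20 was -0.49 (jackknife SE 0.13), against -0.52 (SE 0.15) without it. In size, this median less its SE lies below 0.75 of the unadjusted value. The unadjusted median less its own SE does too, so the bound cannot decide. The covariate also differs between the groups, so the explanation cannot be told apart from a change within cells. Sarcoidosis replicate 6, with an alveolar type 2 mean of -3.77, had a sterol mean of -0.74, and sarcoidosis replicate 1, with -0.89, had -0.81.

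Of 502 measured genes with ZNF symbols, zinc finger genes, 31 rose and 4 fell (6.18% rose, against 2.72% of all genes, and 0.797% fell, against 1.57%), with a median difference of 0.06 (jackknife SE 0.021). The family was chosen after these values were seen and its genes are correlated, so no p-value is given for it. The median was 0.06 after quantile normalisation and 0.07 after subtraction of array medians. Degraded RNA may raise such a family, but its median was 0.07 (0.0705, SE 0.029) with the actin covariate. More T cells could do so too, and the median was 0.068 (0.0679, SE 0.044) with the T cell mean as a covariate. Sarcoidosis replicate 6, with a T cell mean of 1.78, had a family mean of 0.11, inside the range of the other sarcoidosis arrays (0.10 to 0.15). Neither covariate lowered the median, but neither explanation is settled. Each adjusted median less its SE lies below 0.75 of the unadjusted value, and so does the unadjusted median (0.0614, SE 0.021) less its own SE. The bound therefore cannot decide, since a covariate without effect would give the same result. Handling or hybridisation cannot be told apart from group, since the labels name no batch and so 0 batches could be compared within.

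CXCL13, a B cell chemokine, was above 9 in sarcoidosis replicates 4, 5 and 6 (10.62, 9.12 and 9.74) and between 4.43 and 5.43 in the other 3, while normal lung ran from 4.56 to 7.67. The group difference was 2.24 ± 1.10 (adjusted p = 0.267). It was chosen after its values were seen.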
